A study of Mus musculus with 6 samples.

How the data were processed

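Gene expression was measured by RNA sequencing in 6 mouse libraries, 3 labelled WT and 3 labelled KO. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit, per the labels' protocols. The values deposited by the authors are FPKM, fragment counts divided by transcript length and library depth, with 1 table of 21399 gene symbols per library. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical copies cannot be assigned with certainty.

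FPKM values are not counts, so no count model was the main test. The values of each gene were whole multiples of what 1 read was worth in that library, which gave back whole reads. Of 18092 genes examined, 99.98% came out whole in all 6 libraries within 0.002 reads, among them 10729 of the 10732 genes tested. On simulated tables, 97.8% of 848 genes were recovered exactly. A factor common to all 6 counts of a gene cannot be seen this way. The recovered reads summed to 35031169, 35594784 and 33505279 in WT replicates 1 to 3 and to 37137024, 36207266 and 34266095 in KO replicates 1 to 3. FPKM summed to between 391346 and 439451 per library. At this depth a gene such as Ppara, with 1 to 23 reads, has a large counting error, and small differences in it are not detectable.

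Groups were taken from the sample titles. The design, the named-gene rule, 40 gene lists and most alternative settings were fixed before the data were examined. Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1), without further scaling, with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend) and Benjamini-Hochberg adjustment at 0.05. Of the 40 lists, 33 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. The number of members past 0.05 adjusted over the list alone was counted for each. Camera asks whether a list's genes are shifted up or down relative to other genes, and fry whether they move, on balance, in 1 direction. A list whose members go both ways can therefore stay uncalled by either. Single scores were compared with exact two-sided permutation tests, for which 3 against 3 allows no p below 0.1. Principal components were taken over the tested genes, centred per gene.

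The named genes were those past the threshold with groups that did not overlap, up to 15 each way. Since fewer than 5 passed, the 10 highest and 10 lowest by moderated t among genes with groups that did not overlap were named, as not passing where they did not. Ppara, Ptprc and the members with the smallest p of each list, up to 4 for a called list and 2 for another, were named in addition. Some genes that this rule names are not analysed here. Some symbols in the lists were matched to the spelling used in the tables, such as ND1 and COX1 for mitochondrial genes. Positions came from GENCODE M21, an annotation of the mm10 assembly, which held 17801 of the 21399 symbols.

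The gene and list tests were checked on simulated data with the real genes' means and the spread between libraries, drawn independently for each gene. Of 200 genes changed among 10732, 45% were recovered at 1.5-fold with 8 false calls, 83.5% at 2-fold with 4 and 98% at 4-fold with 12. With no change simulated, 0 genes and 0 lists were called, and a complement list raised 2-fold was called with an adjusted p of 8.8e-24. Real genes vary together across libraries, which this simulation leaves out. The folds were set on log2(FPKM + 1), so for low genes they stand for larger folds in FPKM. The changed genes were drawn at random from all genes tested, so the shares recovered do not hold for every set of genes.

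The alternative settings fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, rescaling to a common total with and without mitochondrial and ribosomal protein genes, median-of-ratios scaling, quantile normalization, array weights, fits without trend or with robust variance, the replicate number as a block, other thresholds, and leaving out each library in turn. After the data were seen, a fit with the mean level of 10 core macrophage genes as a covariate and limma's voom on the recovered reads were added, together with lists of core macrophage, B-1 cell and follicular B cell genes. Replicate numbers shared by the groups were checked for pairing by correlating the libraries' deviations from their group means. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Splice forms, the deleted exon and the CD45 alleles were not analysed here, because gene-level values do not hold them.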

Results

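RNA sequencing libraries from a mouse co-culture of primary microglia and peritoneal macrophages were compared between 3 libraries labelled WT and 3 libraries labelled KO. According to the series' design text, microglia from WT or KO mice were deprived of oxygen and glucose, a cell model of ischaemia, and then returned to oxygen and glucose together with peritoneal macrophages of another donor strain. The macrophages came from mice carrying the CD45.1 form of the leukocyte surface protein CD45, and the microglia from mice carrying the CD45.2 form, so that the 2 kinds of cell could be separated by sorting. The design text calls the sorted and sequenced population microglia but gives it the CD45.1 mark, which it assigns elsewhere to the added macrophages. Every sample's label names both cell types as its source, so which cells were sequenced was not settled by the descriptions. The labels do not name the deleted gene, and the series title names PPARα, a nuclear receptor that activates fatty acid oxidation genes and is encoded by Ppara. They also do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Each library listed 21399 genes in FPKM, and the reads recovered from these values summed to between 33505279 and 37137024 per library.

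Ppara, on chromosome 15 from 85734983 to 85802819 on the plus strand of mm10, was near the detection limit in every library. The WT libraries held 11, 1 and 2 Ppara reads (0.0290, 0.00259 and 0.00551 FPKM) and the KO libraries held 13, 23 and 10 reads (0.0325, 0.0588 and 0.0270 FPKM). The mean was 4.67 ± 5.51 reads in WT and 15.3 ± 6.81 reads in KO (SD, n = 3), and an exact two-sided permutation test on the reads gave p = 0.2, where 0.1 is the smallest p that 3 against 3 allows. The mean FPKM was 3.19 times as high in KO. Ppara lay below the filter of 1 FPKM and was added to the genes tested for this purpose. On the log2(FPKM + 1) scale the difference was 0.04, with an adjusted limma p of 0.88, because at such low values the added 1 removes almost all of it. It was 0.31 with 0.1 added instead and -0.11 with quantile normalization. By voom on the recovered reads, chosen after the data were seen, it was 2.05 with an unadjusted p = 0.025, beside the exact permutation p = 0.2. No setting called the gene lower in the libraries labelled KO. These gene-level values do not check the labels, because a deletion of part of a gene can leave reads and because the added macrophages would carry the intact gene. The 2 groups are accordingly called the libraries labelled WT and KO.

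The question of which cells contributed RNA was addressed with marker lists fixed before the data were examined. B cell genes were abundant in all 6 libraries, with a median of 320 to 424 FPKM per library over 10 markers. Cd79a, a subunit of the B cell receptor, stood at 2062 ± 155 FPKM in WT and 1757 ± 70.4 FPKM in KO (SD, n = 3), rank 25 among all genes by mean level. T and NK cell markers had medians of 10.5 to 17.9 FPKM over 12 genes. Microglia markers had medians of only 0.345 to 1.09 FPKM over 21 genes, and 6 of these genes reached 1 FPKM in every library. Tmem119, a microglial surface protein, stood at 0.567 ± 0.427 FPKM in WT and 2.27 ± 0.148 FPKM in KO. The microglial receptor P2ry12 and the microglial transcription factor Sall1, named after their values were seen, reached at most 1.09 and 0.152 FPKM in any library. Peritoneal macrophage markers had medians of 4.56 to 8.18 FPKM over 22 genes in the WT libraries and of 15.2 to 31.9 FPKM in the KO libraries. Ptprc, which encodes CD45, stood at 251 ± 40.8 FPKM in WT and 220 ± 29.0 FPKM in KO, and a gene-level value does not separate its CD45.1 and CD45.2 forms.

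**Figure D1:**
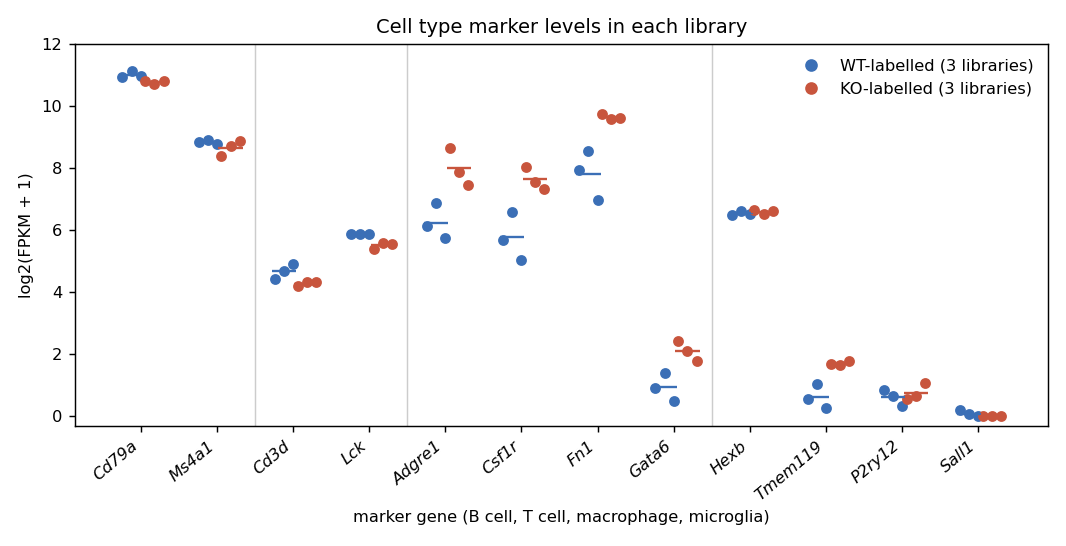
Levels of 12 marker genes in the 6 libraries, as log2(FPKM + 1), with 1 point per library and a short line at each group mean. The B cell gene Cd79a lies highest in both groups, the macrophage genes Adgre1, Csf1r, Fn1 and Gata6 lie higher in all 3 KO libraries than in every WT library, and Tmem119, P2ry12 and Sall1 lie near the bottom.

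Marker scores were taken over the markers with a mean of at least 1 FPKM, 18 of 22 for peritoneal macrophages and 10 of 21 for microglia, so the microglia score leaves out the lower markers. The mean log2(FPKM + 1) of the peritoneal macrophage markers was 3.98 ± 0.53 in WT and 5.38 ± 0.49 in KO (SD, n = 3), a difference of 1.40. That of the microglia markers was 3.03 ± 0.20 in WT and 3.14 ± 0.18 in KO, a difference of 0.11 (exact two-sided permutation p = 0.6). The microglia score minus the peritoneal macrophage score was lower by 1.29 in KO, going from -0.95 ± 0.38 to -2.24 ± 0.64. Its exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows, so this design could not reach 0.05. The first principal component held 63.4% of the variance between libraries, with scores of -19.7, 1.95 and -30.6 in WT replicates 1 to 3 and 29.0, 12.5 and 6.92 in KO replicates 1 to 3. WT replicate 2 thus lay closer to KO replicate 3 than to the other WT libraries on this component.

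The comparison of KO with WT asked which genes differed with the genotype of the microglia in the co-culture. Of 10732 genes tested with limma, 3 were called higher in the libraries labelled KO and 0 were called lower. F5, which encodes coagulation factor V and belongs to the peritoneal macrophage marker list, rose 4.67-fold, from 5.21 ± 0.536 to 24.3 ± 3.85 FPKM (SD, n = 3, log2 fold change 2.02, SE 0.13, adjusted p = 0.0053 by limma). Oscp1, an organic solute carrier partner gene, rose 5.02-fold, from 0.619 ± 0.112 to 3.11 ± 0.424 FPKM (log2 fold change 1.34, SE 0.12, adjusted p = 0.033 by limma). Acpp, which encodes an acid phosphatase, rose 4.02-fold, from 2.97 ± 0.200 to 11.9 ± 2.70 FPKM (log2 fold change 1.68, SE 0.16, adjusted p = 0.034 by limma). Log2 fold changes were taken on log2(FPKM + 1), which understates the change of low genes such as Oscp1. In mm10, F5 lies on chromosome 1 from 164151838 to 164220277 on the plus strand, Oscp1 on chromosome 4 from 126058565 to 126092195 on the plus strand, and Acpp on chromosome 9 from 104288251 to 104337748 on the minus strand. The annotation places a pseudogene inside F5 and another inside Oscp1, and an opposite-strand noncoding gene overlaps F5, while Acpp overlaps no other gene.

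The next genes by the moderated t statistic had groups that did not overlap but did not pass the test. Higher in KO were Cd33, a sialic acid-binding receptor of myeloid cells, at 2.56 ± 0.842 and 11.02 ± 1.97 FPKM in WT and KO, and Olr1, a receptor for oxidised lipoprotein, at 3.23 ± 1.20 and 12.3 ± 0.976 FPKM (SD, n = 3). Itga9, Cacna1d, Frrs1, Rnf149 and Lpar6 completed these 7 genes, with limma adjusted p-values from 0.071 to 0.074 over all 7. On the other side stood Fbxo2 at 1.86 ± 0.614 and 0.336 ± 0.0663 FPKM, Ncan, a proteoglycan of brain matrix, at 1.74 ± 0.492 and 0.547 ± 0.105 FPKM, and Insl3, a relaxin-like hormone, at 13.7 ± 0.997 and 8.87 ± 0.682 FPKM. Gm30135, Gm38639, Tagap1, Gm16973, Mxra8, Gm7609 and Gm2447 completed these 10, with adjusted p-values from 0.077 to 0.11. Cacna1d, Lpar6, Insl3, Gm16973 and Gm7609 overlap a protein-coding gene in the annotation, Mxra8, Itga9, Rnf149 and Tagap1 overlap noncoding genes, and Tagap1 and the Gm-named genes may share reads with near-identical copies, so their values are uncertain.

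At an unadjusted limma p under 0.05, 951 genes were higher and 881 lower, and voom on the recovered reads called 5 higher and 0 lower. The groups did not overlap for 2672 genes, 24.9% of those tested, where chance gives 10% for a single gene. Genes that vary together can separate together, so this excess alone does not show an effect of the group. After the results were seen, the libraries were also split into groups of 3 that mixed the labels. These splits gave 72 to 1335 genes at an unadjusted limma p under 0.05, and the real split 1832. The count of 3 genes depended on single libraries: it was 0 without WT replicate 1, 1 without KO replicate 1, 1 without KO replicate 2, and 514 without WT replicate 2, when 38 genes were also called lower. It was 0 when the level of core macrophage genes entered the model as a covariate, an alternative chosen after the data were seen whose covariate itself differed by 1.45 (log2) between the groups, and 0 when no filter on low values was applied.

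**Figure D2:**
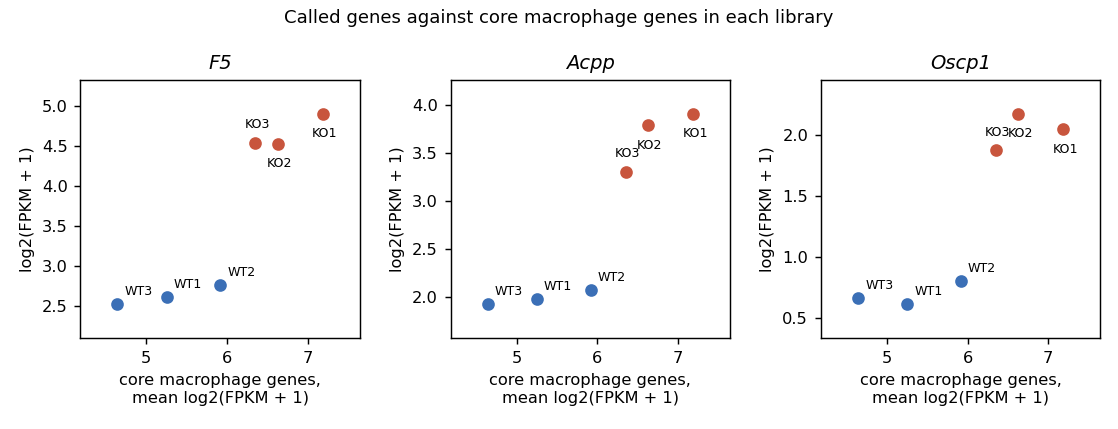
Level of each called gene, as log2(FPKM + 1), against the mean log2(FPKM + 1) of 10 core macrophage genes in the same library, with WT libraries in blue and KO libraries in red. Core macrophage genes were higher by 1.45 (log2) in KO, and the test that called the 3 genes favours a small spread within groups.

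Genes of macrophage identity and clearance were called higher in the libraries labelled KO, as 5 lists, by camera with a preset correlation of 0.01. None of the 5 calls held (adjusted p = 0.338 with an estimated correlation for each), and none was made by fry. Of 18 peritoneal macrophage markers tested, 17 had positive fold changes with a median log2 fold change of 1.59, F5 rose over all genes tested, and 16 passed when adjusted over the list alone. Thbs1, a matricellular protein, stood at 408 ± 161 and 1537 ± 168 FPKM in WT and KO, Itga6 at 20.5 ± 3.83 and 46.5 ± 9.39 FPKM, and Ltbp1 at 5.53 ± 3.07 and 19.6 ± 3.48 FPKM (SD, n = 3). Of 31 phagocytosis and efferocytosis genes, 25 were positive (median 1.20) and 20 passed adjusted over the list alone. Mertk, a receptor for dying cells, stood at 1.78 ± 0.667 and 6.34 ± 1.27 FPKM, its ligand Pros1 at 4.40 ± 2.11 and 13.6 ± 4.94 FPKM, and the scavenging receptor Lrp1 at 10.4 ± 5.37 and 27.3 ± 1.06 FPKM. Of 17 complement genes, 14 were positive (median 1.56) and 12 passed adjusted over the list alone. The complement receptor C3ar1 stood at 13.2 ± 7.02 and 39.4 ± 10.8 FPKM. Of 27 lysosomal genes, 23 were positive (median 0.37) and 4 passed adjusted over the list alone. The proton pump gene Atp6v1a stood at 20.1 ± 1.20 and 34.8 ± 6.48 FPKM and the protease gene Ctsl at 47.2 ± 27.5 and 134 ± 36.4 FPKM. Of 27 genes of the disease-associated microglia signature, 24 were positive (median 0.95) and 14 passed adjusted over the list alone. Cd9 stood at 114 ± 7.88 and 249 ± 62.8 FPKM and the lectin receptor Clec7a at 17.3 ± 5.67 and 73.1 ± 41.0 FPKM.

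With the preset correlation the adjusted p-values of these 5 lists ran from 1.5e-16 for the peritoneal macrophage markers to 2.0e-08 for complement. Without KO replicate 1 the median of the disease-associated microglia signature was 0.57 and that of the lysosome 0.20. Apart from F5, no member of these lists passed over all genes tested. The 5 calls are not separate findings, because lists share members: Ctsl and Cd68, for example, are on both the lysosome and the disease-associated microglia lists. The peritoneal macrophage score, which is the mean over the peritoneal macrophage markers themselves, differed by 1.40 (log2) between the groups.

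**Figure D3:**
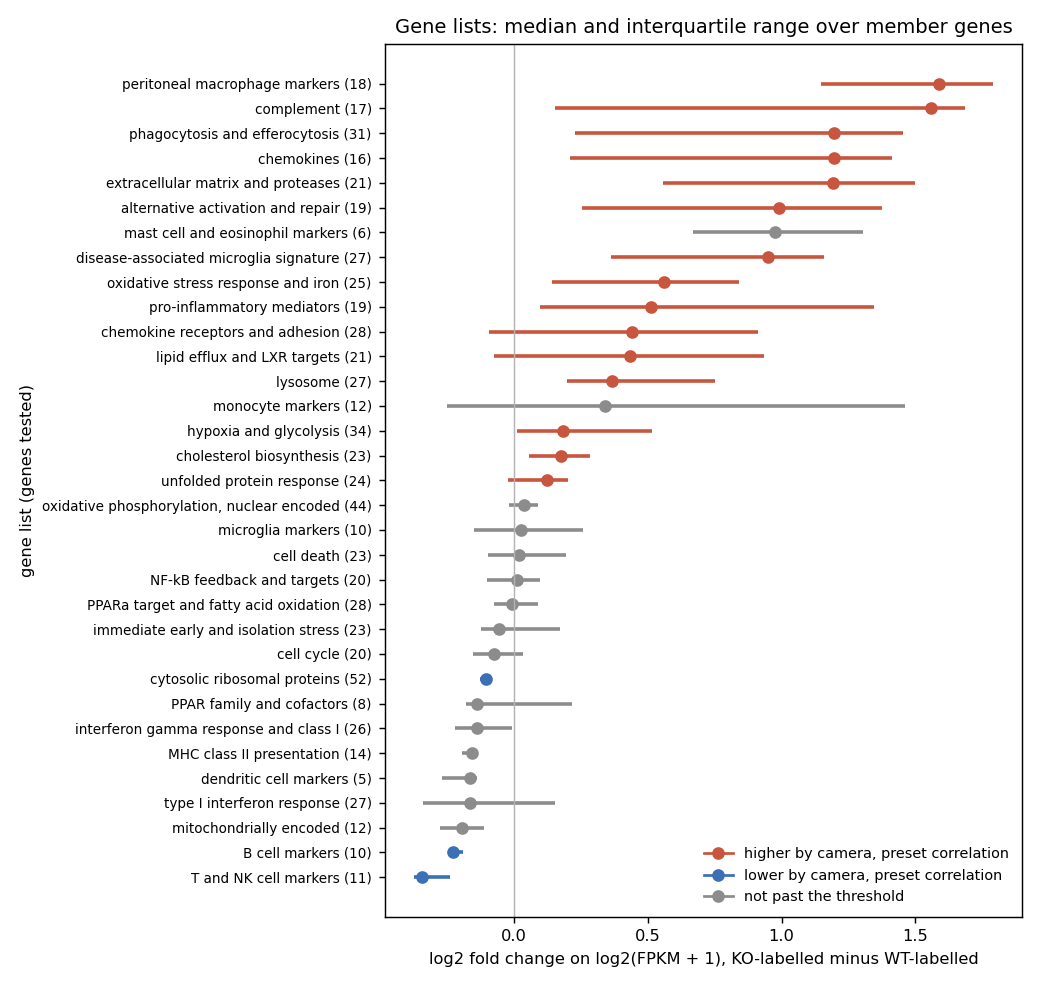
Median log2 fold change (KO-labelled minus WT-labelled) of each of 33 gene lists, as a point, with the interquartile range over its member genes as a line, and lists in red or blue called higher or lower by camera with a preset correlation, none of which held with an estimated one. The medians near 0 of the microglia, PPARα target, NF-kB, oxidative phosphorylation, cell death and immediate early lists change sign under at least 1 other scaling.

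Inflammatory, chemotactic and matrix genes were also called higher, as 5 lists, by camera with the preset correlation. None of these calls held (adjusted p = 0.338 with an estimated correlation for each), and none was made by fry. All 21 genes of extracellular matrix and its proteases had positive fold changes (median 1.19), and 15 passed adjusted over the list alone. Serpinb2, an inhibitor of plasminogen activators, stood at 155 ± 72.4 and 521 ± 152 FPKM in WT and KO (SD, n = 3). Of 19 genes of alternative activation and repair, 17 were positive (median 0.99) and 8 passed adjusted over the list alone. The growth factor gene Vegfa stood at 4.82 ± 0.778 and 11.3 ± 1.95 FPKM and Fn1, fibronectin, at 247 ± 124 and 803 ± 43.8 FPKM. All 16 chemokines were positive (median 1.20) and 5 passed adjusted over the list alone. Cxcl16 stood at 22.1 ± 7.14 and 48.1 ± 11.5 FPKM and Pf4 at 447 ± 286 and 1305 ± 477 FPKM. Of 19 pro-inflammatory mediators, 16 were positive (median 0.51) and 7 passed adjusted over the list alone. The cytokine gene Il1b stood at 60.1 ± 26.5 and 180 ± 23.4 FPKM and the inflammasome sensor Nlrp3 at 3.54 ± 1.60 and 9.96 ± 1.39 FPKM. Of 28 chemokine receptor and adhesion genes, 18 were positive (median 0.44), and 14 higher and 1 lower passed adjusted over the list alone. The integrin gene Itgam stood at 103 ± 38.4 and 285 ± 49.6 FPKM. With the preset correlation the adjusted p-values ran from 9.6e-14 for matrix to 9.1e-06 for receptors and adhesion. The chemokine median was 0.67 without KO replicate 1, 0.52 with totals rescaled without mitochondrial and ribosomal genes and 0.23 with no filter. The median of the pro-inflammatory mediators was 1.25 with the filter at 5 FPKM and 0.25 with no filter, and it was 0.33 without KO replicate 1, 0.77 without WT replicate 2 and 0.82 without KO replicate 3. The receptor and adhesion median was 0.22 with no filter, 0.28 with a pseudocount of 5 and 0.49 under median-of-ratios scaling. No single member passed over all genes tested, and the peritoneal macrophage score differed by 1.40 (log2) in the same direction. These lists share members with others, so their calls are not separate findings. Fn1 is also on the peritoneal macrophage and matrix lists and enters that score, and Itgam is also on the complement list.

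Lists of stress, lipid and sugar metabolism were also called higher by camera with the preset correlation. No call held (adjusted p = 0.338 with an estimated correlation for 4 lists and adjusted p = 0.529 with an estimated correlation for the unfolded protein response), and none was made by fry. Of 25 genes of the oxidative stress response and iron handling, 24 were positive (median 0.56) and 6 passed adjusted over the list alone. The regulator Nfe2l2 stood at 20.4 ± 1.11 and 29.9 ± 3.99 FPKM and glutathione reductase, Gsr, at 14.4 ± 5.63 and 41.6 ± 17.1 FPKM in WT and KO (SD, n = 3). Of 34 hypoxia and glycolysis genes, 27 were positive (median 0.18) and 4 passed adjusted over the list alone. The oxygen-sensing factor Hif1a stood at 43.6 ± 7.42 and 69.5 ± 2.43 FPKM and Hk2, hexokinase, at 3.45 ± 0.857 and 6.89 ± 0.850 FPKM. Of 23 cholesterol synthesis genes, 19 were positive (median 0.18) and 3 passed adjusted over the list alone. Insig1, a brake on the pathway, stood at 20.3 ± 1.70 and 27.8 ± 2.31 FPKM. Of 21 lipid efflux and LXR target genes, 14 were positive (median 0.44) and 0 passed adjusted over the list alone. The exporter Abca1 stood at 24.5 ± 7.59 and 43.4 ± 4.30 FPKM and the scavenger receptor Cd36 at 19.5 ± 6.66 and 53.7 ± 29.8 FPKM. Of 24 unfolded protein response genes, 16 were positive (median 0.12) and 0 passed adjusted over the list alone. Its members with the smallest p went both ways, with Atf3 at 4.62 ± 1.65 and 10.02 ± 3.14 FPKM and Ddit3 at 12.6 ± 1.13 and 9.98 ± 0.603 FPKM. With the preset correlation the adjusted p-values ran from 4.8e-10 for oxidative stress to 0.020 for the unfolded protein response. The lipid efflux median was 0.24 without KO replicate 1, and the hypoxia median 0.29 without WT replicate 2. The unfolded protein response call also ended without WT replicate 3, without KO replicate 1, with array weights, and with totals rescaled without mitochondrial and ribosomal genes (adjusted p from 0.0025 to 0.38 over all settings with the preset correlation). The peritoneal macrophage score was higher in KO by 1.40 (log2).

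Lymphocyte markers and ribosomal protein genes were called lower, as 3 lists and by small amounts, by camera with the preset correlation. None of the calls held (adjusted p = 0.338 with an estimated correlation for both lymphocyte lists and adjusted p = 0.695 with an estimated correlation for the ribosomal list), and none was made by fry. All 11 T and NK cell markers had negative fold changes with a median of -0.34, and 1 passed adjusted over the list alone. The T cell kinase Lck stood at 57.4 ± 0.362 FPKM in WT and 44.6 ± 3.36 FPKM in KO, and Cd3d at 24.6 ± 4.42 and 18.4 ± 1.04 FPKM (SD, n = 3). All 10 B cell markers were negative (median -0.23) and 0 passed adjusted over the list alone, with Cd22 at 308 ± 19.6 and 254 ± 28.6 FPKM. All 52 cytosolic ribosomal protein genes were negative (median -0.10, where the median of all genes tested was -0.06), and 0 passed adjusted over the list alone. With the preset correlation the adjusted p-values were 8.9e-04, 0.0037 and 0.018 in that order. The ribosomal call also ended without a filter, under median-of-ratios scaling and without WT replicate 2, WT replicate 3 or KO replicate 2, and the ribosomal median was -0.19 without WT replicate 1, -0.07 without WT replicate 2, -0.05 without WT replicate 3 and -0.04 under median-of-ratios scaling.

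Genes of the pathway named in the series title were not called as a group. Ppara had 1 to 23 reads per library, microglia marker medians were 0.345 to 1.09 FPKM, and added macrophages would carry the intact gene. The result therefore does not show how a loss of PPARα in microglia affects these genes. Of 28 PPARα target and fatty acid oxidation genes tested, 13 had positive and 15 negative fold changes, and 0 passed, over all genes or adjusted over the list alone. The list's median log2 fold change was -0.01 (interquartile range 0.17) and its mean 0.05, so the sign differed between them (camera adjusted p = 0.21). The median was 0.06 both under median-of-ratios scaling (adjusted p = 0.11) and without WT replicate 2 (adjusted p = 0.074), and it was also above 0 without KO replicate 2 and without KO replicate 3. Its members with the smallest p were Plin2, a lipid droplet coat protein, at 14.6 ± 5.56 and 34.1 ± 13.2 FPKM in WT and KO, and the peroxisomal enzyme Hsd17b4 at 19.4 ± 1.88 and 23.97 ± 0.882 FPKM (SD, n = 3). Among 8 genes of the PPAR family and cofactors, 3 were positive and 0 passed on either adjustment (median -0.14, mean 0.10, camera adjusted p = 0.75), with Rxra, the partner receptor of PPARs, at 3.63 ± 1.53 and 7.80 ± 2.15 FPKM. The median of this list was -0.02 without KO replicate 1, -0.04 without WT replicate 1 and -0.06 without WT replicate 3.

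Other lists were not called either, although several were called under other settings. Among 12 monocyte markers, 6 higher and 4 lower passed adjusted over the list alone. Vcan stood at 8.17 ± 2.64 and 27.5 ± 4.96 FPKM and F13a1 at 17.98 ± 8.998 and 60.9 ± 10.1 FPKM in WT and KO (SD, n = 3, camera adjusted p = 0.082). Of 10 microglia markers tested, 6 were positive with a median of 0.03 that changed sign under quantile normalization and with totals rescaled without mitochondrial and ribosomal genes, and 1, Tmem119, passed adjusted over the list alone (camera adjusted p = 0.17). The type I interferon response had 10 positive and 17 negative genes and a median of -0.17, and 0 passed adjusted over the list alone (camera adjusted p = 0.93). It was called higher without KO replicate 3 (adjusted p = 0.0498) and lower without WT replicate 3 (adjusted p = 0.026), and its leading genes went both ways, with Ifitm3 at 165 ± 98.2 and 439 ± 197 FPKM and Stat2 at 42.3 ± 7.26 and 32.1 ± 3.54 FPKM. The interferon gamma and class I list had 21 negative genes of 26 and 0 passed adjusted over the list alone (median -0.14, camera adjusted p = 0.089), with H2-Q4 at 251 ± 17.4 and 206 ± 2.49 FPKM. MHC class II presentation had 12 negative genes of 14, and 1 gene, the costimulator Cd86, passed higher adjusted over the list alone, at 23.8 ± 0.623 and 32.4 ± 3.80 FPKM (median -0.16, camera adjusted p = 0.18). NF-kB feedback genes and immediate early genes each had 3 members higher adjusted over the list alone, with medians of 0.01 and -0.06 that changed sign under other scalings and means of 0.18 and 0.10 (camera adjusted p = 0.14 and 0.22). Tnfaip2 stood at 9.41 ± 4.02 and 27.4 ± 9.48 FPKM and Fos, an immediate early transcription factor, at 21.03 ± 8.33 and 52.3 ± 11.4 FPKM. Dendritic cell markers (5 genes, median -0.16), cell death (23 genes, 0.02), cell cycle (20 genes, -0.07), nuclear genes of oxidative phosphorylation (44 genes, 0.04), mitochondrially encoded genes (12 genes, -0.19) and mast cell and eosinophil markers (6 genes, 0.98) had 0 members passing adjusted over the list alone. Their camera adjusted p-values were 0.082, 0.13, 0.60, 0.054, 0.23 and 0.081 in that order, and the medians of cell death and oxidative phosphorylation changed sign when totals were rescaled without mitochondrial and ribosomal genes. When 1 library was left out, the mitochondrially encoded median ran from -0.26 (without KO replicate 3) to -0.08 (without KO replicate 1).

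Calls of these lists under other settings depended on scaling, the filter, weights, the replicate block and single libraries. Monocyte markers were called higher with totals rescaled to a common value, with and without mitochondrial and ribosomal genes. They were also called higher with array weights, with the replicate block and without KO replicate 3 (camera adjusted p from 0.017 to 0.049 over these settings). Mast cell and eosinophil markers were called higher with totals rescaled without mitochondrial and ribosomal genes, with array weights and without WT replicate 2, WT replicate 3 or KO replicate 3 (adjusted p from 0.0050 to 0.027), while their median was -0.39 without WT replicate 1. The interferon gamma and class I list was called lower with both rescalings of totals, with array weights and without WT replicate 3 or KO replicate 1 (adjusted p from 0.0022 to 0.049). Oxidative phosphorylation was called higher with the filter at 5 FPKM, under median-of-ratios scaling, with array weights and without WT replicate 2 or KO replicate 2 (adjusted p from 4.9e-05 to 0.040). NF-kB feedback genes were called higher without KO replicate 1 (adjusted p = 0.032), and cell death and immediate early genes without WT replicate 2 (adjusted p = 0.033 and 0.049). With the core macrophage covariate, which itself differed between the groups, 6 lists were called lower. They were type I interferon (median -1.02, adjusted p = 4.9e-08), interferon gamma (-0.27, 5.7e-04), oxidative phosphorylation (-0.21, 5.7e-04) and, opposite to their calls without it, chemokines (-0.58, 0.0014), the unfolded protein response (-0.22, 0.0030) and the lysosome (-0.22, 0.044).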

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

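The fit with core macrophage genes as a covariate and voom on the recovered reads were chosen after the results were seen. The 3 genes called higher in the libraries labelled KO became 6 with a pseudocount of 5, 0 without a filter, when 21399 genes were tested, 544 with array weights, 11 with the replicate block, 0 with the macrophage covariate and 5 with voom. They became 47 at an adjusted p under 0.1 and 951 at an unadjusted p under 0.05. The 0 genes called lower became 68 with array weights, 3 at an adjusted p under 0.1 and 881 at an unadjusted p under 0.05. Leaving out 1 library gave 0 (without WT replicate 1) to 514 (without WT replicate 2) genes higher and 0 to 38 (without WT replicate 2) lower, with 1 higher without KO replicate 1 or KO replicate 2 and 1 lower, Gfap, without WT replicate 3. The 15 lists called higher became 0 with the macrophage covariate, 0 with an estimated correlation and 0 by fry, and the 3 called lower became 6, 0 and 0. None of the original 3 was among the 6, and chemokines, lysosome and unfolded protein response turned from called higher to called lower. The covariate differed by 1.45 (log2) between the groups, and Cd68, Fcgr1, Lyz2 and Sirpa among its genes are members of tested lists, so the loss of list calls with it was largely set by its construction, and the cause of the changed directions was not tested. Leaving out 1 library gave 15 to 19 lists higher and 2 to 4 lower, and apart from those 3 settings 16 to 18 of the 18 calls held. Deviations of same-numbered libraries correlated at -0.21, -0.38 and 0.27, which gave no common direction, and 3 such correlations cannot exclude pairing. With the replicate block, 16 lists were called higher, the monocyte markers newly so (adjusted p = 0.017), and all 18 calls held. The difference in Ppara was -0.11 with quantile normalization and 2.05 with voom, where it passed an unadjusted threshold of 0.05, and 0.02 to 0.05 when 1 library was left out. The difference in marker scores ranged from -1.58 to -0.94 when 1 library was left out. Of 2295 values of single genes under an alternative, 2102 kept direction and side of the threshold, 146 passed it newly, 17 lost it and 30 changed sign. With the macrophage covariate, the log2 fold changes that changed sign were 0.29 for Ptprc, -0.16 for Plin2, -0.11 for Rxra, -0.22 for Nr1h3, 0.18 for Dpp4, 0.0121 for Blk, 0.0646 for Cd8a, -0.16 for Kit, -0.66 for Tpsb2, -0.15 for Cxcl2, -0.18 for Pf4, -0.64 for Ifitm3, -0.0539 for C5ar1, -0.0048 for Ctsl, -0.0553 for Gusb, -0.22 for Cd36, -0.32 for Pltp, -0.34 for Uqcrq, -0.12 for Atf3, -0.0481 for Cdkn1a, -0.38 for Tnfrsf1a, -0.19 for Mmp8, 0.0727 for Krt8, -0.67 for Aldh1l1, 0.13 for Pecam1, 0.0709 for Eif2s3y and 0.87 for Xist. When 1 library was left out, Tpsb2 ranged from -0.27 (without WT replicate 1) to 2.46, Aldoc from -0.23 to 0.0098 (without WT replicate 1) and Aldh1l1 from -0.10 (without WT replicate 3) to 0.42. None of these genes passed the test in either fit, and the cause of the changes was not tested. At 33505279 to 37137024 reads, depth limits Ppara and other genes with few reads.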

Other observations

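Of the tests reported in this part, those of the splits and of the macrophage genes were chosen after the results were seen, and that of B-1 cells was written before its result was seen. Markers of cells that few lists could test varied from library to library. Mast cell proteases were lowest in WT replicate 1 and next lowest in KO replicate 3. Tpsb2 stood at 3.21 FPKM in WT replicate 1, against 183 and 80.3 FPKM in WT replicates 2 and 3 and 166, 164 and 37.3 FPKM in KO replicates 1 to 3. Col1a1, a fibroblast collagen, stood at 6.92 FPKM in WT replicate 2, 5.13 in KO replicate 2 and 14.2 in KO replicate 3, and at 0.339 to 1.17 FPKM in the other libraries. The astrocyte filament gene Gfap had 724, 738 and 1 reads in WT replicates 1 to 3 and 62, 27 and 20 reads in KO replicates 1 to 3, and the oligodendrocyte lineage gene Olig1 had 86, 32 and 49 reads against 14, 5 and 10. Ncan, a brain proteoglycan, had 582, 332 and 432 reads against 119, 153 and 163. Gfap and Olig1, singled out after their values were seen, had means below 1 FPKM and were not tested.

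Lists with fewer than 5 tested genes gave single values. Csf3r and Mmp8, on the neutrophil list, stood at 8.66 ± 4.29 and 27.8 ± 6.97 FPKM and at 3.12 ± 1.89 and 8.54 ± 3.38 FPKM in WT and KO (SD, n = 3). Krt8, on the mesothelial and fibroblast list, stood at 3.38 ± 0.528 and 2.81 ± 0.496 FPKM, and Aldoc, on the astrocyte list, at 3.87 ± 0.833 and 3.57 ± 0.181. Cnp, on the oligodendrocyte list, stood at 187 ± 18.5 and 167 ± 8.78, and Tubb3, on the neuron list, at 2.34 ± 0.583 and 2.00 ± 0.258. Pecam1, on the endothelial list, stood at 69.1 ± 3.96 and 62.9 ± 8.40 FPKM. The median marker per library stood at only 0.060 to 0.535 FPKM for the oligodendrocyte list. It was 0 to 0.0354 FPKM for the neuron list and 0.052 to 0.084 FPKM for the endothelial list. The levels of Cnp and Pecam1 therefore do not show RNA of oligodendrocytes or endothelium. Xist, expressed in female cells, stood at 41.6 ± 14.8 and 33.2 ± 9.01 FPKM and Eif2s3y, on the Y chromosome, at 4.35 ± 0.438 and 3.55 ± 0.459 FPKM, so every library held RNA of both sexes. None of these genes passed limma's test.

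The higher macrophage genes in the libraries labelled KO may reflect a larger share of macrophage RNA among the sequenced cells. A lower share of B cell RNA alone would raise all other cell types, and the direction of the values argues against it. The 11 T and NK cell markers had a median log2 fold change of -0.34. The interquartile range of 0.13 is over genes that vary together and does not measure the spread between libraries. Their mean log2(FPKM + 1) was 4.34 ± 0.17 in WT and 4.03 ± 0.09 in KO (SD, n = 3, exact permutation p = 0.1, the smallest possible). A higher macrophage share would move macrophage genes together, and the 14 of 18 tested peritoneal macrophage markers with a mean of at least 5 FPKM differed from 10 core macrophage genes by a median of 0.11 (log2, interquartile range 0.36). The core genes were higher by a median of 1.61 and spread from 0.70 to 2.03, so their measured folds were unequal. The cause of this spread was not tested. For the 3 called genes the tests disagree, and a macrophage share cannot be told apart from a change of their own. On log2(FPKM + 1), which understates low genes, the ratios of all 3 to the core genes overlapped between the groups (exact permutation p = 0.2 for F5, 0.7 for Acpp and 0.9 for Oscp1). As plain FPKM over the relative level of the core genes, the ratios of Acpp and Oscp1 overlapped (exact permutation p = 0.3 and 0.2). That of F5 did not, at 7.26 to 14.5 in WT and 14.6 to 20.5 in KO (exact permutation p = 0.1, the smallest possible). With the core genes as a covariate the log2 fold changes stayed at 1.62 (SE 0.16) for F5, 1.28 (SE 0.25) for Acpp and 1.16 (SE 0.21) for Oscp1, from 2.02 (SE 0.13), 1.68 (SE 0.16) and 1.34 (SE 0.12). Their calls ended with adjusted p-values of 0.198, 0.475 and 0.475 (0.000513 to 0.198 for F5 over all settings) because the folds shrank and the errors grew. The 3 genes were picked by a test that favours a small spread within groups, which also limits what this fit shows. A change in the macrophages brought about by the KO microglia stays open, since this design does not separate the number of macrophages from their expression.

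With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 is possible for either count. The real split gave 3 genes and no other split gave more than 0, so 1 of the 10 reached that count. The real split called 18 lists and the highest other split 21, so 4 of the 10 reached that count.

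The B cell genes among the most abundant transcripts might come from peritoneal B-1 cells that accompany macrophages in peritoneal washes. A gate on CD45.1 alone would not remove them, and the labels name no such cells. All 8 genes of a B-1 list were at 1 FPKM or more in all 6 libraries, with Zbtb32 at 55.2 ± 8.07 and 46.3 ± 5.60 FPKM and Fcrl5 at 56.4 ± 3.56 and 51.5 ± 9.68 FPKM in WT and KO (SD, n = 3). Cd9 of the B-1 list is also on the disease-associated microglia list. The median B-1 gene lay below the median of 4 follicular B cell genes in every library, at 32.7 to 39.0 against 45.7 to 63.6 FPKM, which argues against B-1 cells as the only B cells. A mixture of B cell kinds stays open, as does the tissue they came from.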
